A study of Oryza sativa with 12 samples.

How the data were processed

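Total RNA from rice embryos (Oryza sativa, cultivar Dongjin) was measured on 12 Affymetrix RJpGene-1_1-st arrays, 2 for each of 6 conditions. Embryos germinated in darkness for 24 h, at a temperature of 28 °C, in 10 mM calcium chloride with 60 mM glucose (Glc) or 60 mM mannitol (Mtl), a sugar alcohol that sets the osmotic strength without serving as glucose. In the conditions GlcDNP and MtlDNP the medium also held 0.08 mM 2,4-dinitrophenol (DNP), an uncoupler that lets protons leak across the inner mitochondrial membrane, used by the submitters to lower cellular energy in air. The labels do not spell out AC in GlcAC and MtlAC. The protocol describes 1 further incubation, in which embryos were submerged in medium flushed with nitrogen, and AC is read here as that anaerobic incubation. The name AC is kept for that reason.

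The log2 expression values are those deposited by the submitters in 1 table of 36643 probe sets (called probes here) and 12 arrays. Per the labels, they are RMA values from Expression Console at the core level; RMA corrects the background, gives arrays a common distribution of probe intensities and summarizes each probe set. Affymetrix Power Tools is named in the submitters' processing notes. Versions, genome build and annotation are not given in the sources used here, nor is the base of the logarithm, which was taken as 2 from the range of the values, -0.49 to 13.12. No value was missing and every column of values was used. For arrays, the number of arrays limits the precision.

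The design text calls the replicates technical and speaks of 6 rice samples. The 2 arrays of a condition may therefore hold the same RNA. The p-values of the contrasts and list tests below measure the spread between arrays, not between separate batches of embryos. A size threshold was added to each test for that reason. Replicate numbers in the labels are not said to mark a shared batch, so the fits had no replicate block.

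Probes were named through the platform's probe-to-gene table. Of the probes, 24161 had 1 gene, 90 had several and 12392 are unnamed here. All 24161 were found by gene number in the RefSeq gene table (assembly GCF_034140825.1), which served only for names. No coordinates are printed because the build behind the array's probes is not given. An informative symbol or synonym was available for 2735 of these probes, and only they could be named. The rule for named genes asked for a product description; with none in the tables used, an informative symbol or synonym took its place.

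Differences were tested with limma 3.58.1 in R 4.3.3 on all 36643 probes, with 1 coefficient per condition over all 12 arrays, empirical Bayes without trend, 6 residual and 3.82 prior degrees of freedom, and Benjamini-Hochberg adjustment over probes. A probe was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1, a fold of 2. The 9 contrasts were glucose over mannitol in air, with DNP and under AC; DNP over no DNP and AC over air with each sugar; and the interactions of sugar with DNP and with AC, which are the glucose-over-mannitol difference in that environment minus that in air. An additive model of sugar and environment was also fitted with limma to the 6 condition means, with 2 residual degrees of freedom, and gives 3 results across conditions. Its p-values and errors measure the spread of condition means around the additive model, which includes any interaction of sugar and environment. Errors of differences are standard errors (SE), and levels are mean ± SD of the 2 arrays. All conditions were sampled at 24 h and none earlier. Rose and fell therefore mean higher and lower than in the condition compared, not a change over time.

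Genes named are, per contrast, the 8 called probes with the largest and the 8 with the smallest log2 difference whose arrays lay apart between the groups and which had 1 named gene (5 each way for interactions and the additive fits), and up to 4 members with the largest absolute difference of each gene list described. This rule, the designs, the alternatives and 32 gene lists were fixed before the data were examined. The lists had been written as identifiers and description patterns that the tables used here do not hold. Members were therefore matched by symbol and synonym patterns, written after the tables were seen but before any difference was computed. Lists hold the members with a usable symbol and are incomplete. Rankings below, such as largest and smallest, are likewise among the genes that could be named, and other probes may differ more. Which lists are described was chosen after their tests were seen, and further lists were added to the description, mostly for the closing section, after their values were seen. The 8 genes plotted were picked, after their values were seen, from genes the rule names. The 28 lists with at least 3 measured members were tested with camera (limma) at a preset correlation of 0.01, adjusted over lists within a contrast, and again with the correlation estimated. Counts of called members are given with the adjustment over all probes and adjusted over the list alone.

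Overlaps of responses were counted per direction and set beside 100 simulations of unchanged groups and beside the overlap of independent lists. The test was checked on simulated data for glucose over mannitol in air, with 200 of 36643 probes changed. It recovered 4.5% of them at a simulated log2 change of 1, 72.5% at 1.5, 90.5% at 2 and 98.5% at 3, with 2, 10, 13 and 8 false calls. Changes near the threshold of 1 were thus mostly missed in that simulation.

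Alternatives were median-centring of arrays, quantile re-normalization of the deposited table, leaving out dim probes (22278 kept), empirical Bayes with trend and robust, no size threshold, limma's treat against a fold of 1.5, fitting the compared groups alone, a replicate block, leaving out each array, and averaging arrays with no test. The additive fits were repeated on all 12 arrays and on single replicates. The value tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.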

Results

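The transcriptome of germinating rice embryos was measured in 6 conditions that combined glucose or mannitol with air, the uncoupler DNP or AC, with 2 arrays per condition. The series title asks how adjustments to sugar, cellular energy and oxygen compare. Array medians lay between 3.231 and 3.311 on the log2 scale. The SD of values within an array was 1.808 to 1.857 in air without DNP, 1.639 to 1.675 with DNP, 1.767 and 1.774 in GlcAC and 1.668 and 1.682 in MtlAC. Across all probes, the 2 arrays of a condition correlated at 0.95 to 0.976. The first principal component held 48.8% of the variance and set the air arrays, at -72.94 to -96.17, apart from the DNP arrays, at 59.15 to 75.63. GlcAC lay between them at -8.795 and -12.5, and MtlAC nearer to the DNP arrays at 44.96 and 50.76. The second component, with 10.9%, set the 4 AC arrays, at -34.95 to -47.41, apart from the others. Because the design text calls the replicates technical, the contrasts and list tests measure the spread between arrays only. The additive fits instead measure the spread of condition means around the additive model.

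**Figure D1:**
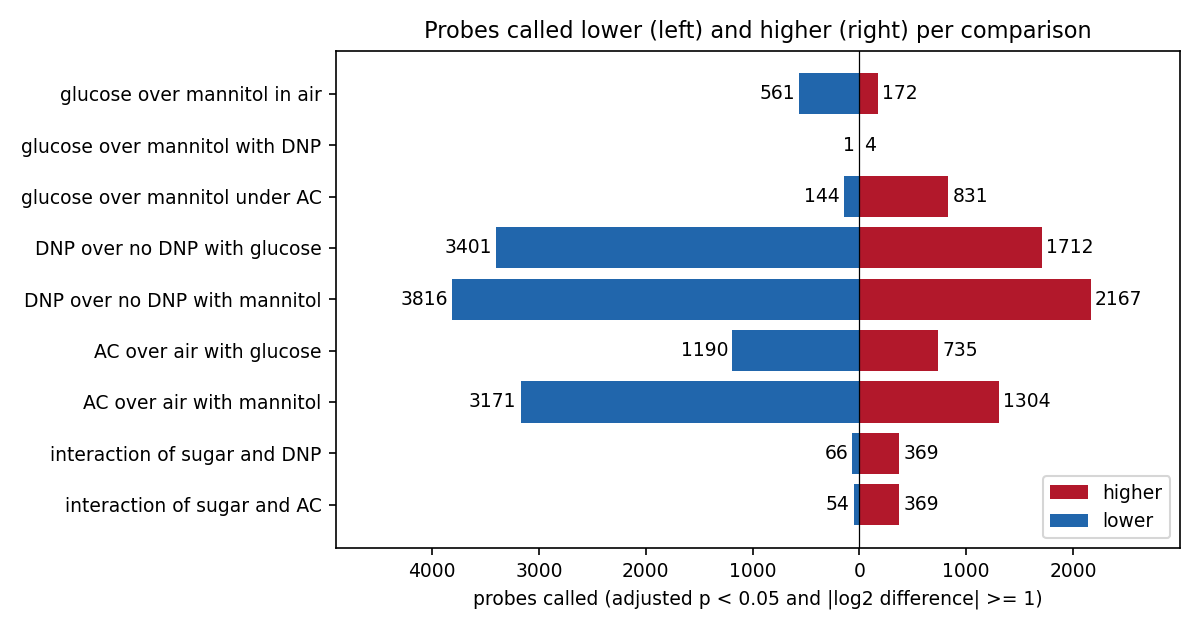
Number of probes called lower (left of 0) and higher (right of 0) in each of 9 comparisons, at an adjusted p under 0.05 and an absolute log2 difference of at least 1. DNP called the most probes (5113 with glucose and 5983 with mannitol), and glucose against mannitol with DNP called 5.

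To find which genes responded to sugar in air, embryos on glucose were compared with embryos on mannitol. The alpha-amylase gene RAmy3D (also AMY1.3, LOC4345814) stood at 3.3 ± 0.085 with glucose and 7.82 ± 0.0093 with mannitol (SD, n = 2 arrays each), 23.0-fold lower with glucose (log2 difference -4.52 ± 0.16, adjusted p = 1.87e-06). The protein kinase gene CIPK15 (LOC4349594) stood at 1.15 ± 0.23 with glucose and 5.84 ± 0.2 with mannitol (-4.70 ± 0.33, adjusted p = 6.16e-05). Its level with glucose lay close to the 5th percentile of those arrays, 1.012, and is not shown to be above background. The size of its difference is therefore not settled. ICL, which encodes isocitrate lyase of the glyoxylate cycle, was 14.9-fold lower (-3.90 ± 0.22, adjusted p = 1.82e-05). The trehalose-6-phosphate phosphatase gene OsTPP1 fell by 2.90, and the glutamate dehydrogenase gene GDH2 fell by 1.90. Of 40 DNA replication genes 6 were called higher with glucose and none lower. They included the origin recognition complex genes ORC6 (1.45 ± 0.25) and ORC3 (1.36 ± 0.24, dim with mannitol at 1.79). The test of this list gave a camera adjusted p = 7.86e-10, and adjusted p = 0.117 with an estimated correlation.

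In total 733 of 36643 probes were called, 172 higher and 561 lower with glucose. Besides ORC6, the named genes with the largest increases were Os-UGD4, a UDP-glucose dehydrogenase gene (2.05), HSF22 (1.86), the cinnamyl alcohol dehydrogenase genes CAD7 (1.79) and CAD8A (1.66), the nitrate transport partner gene NAR2.2 (1.66), MEAL1 (also MEL1, 1.56) and the homeobox gene OsWOX9 (1.45). The named genes with the largest decreases also included the vacuolar aquaporin gene OsTIP2;2 (-3.65), ASMT of melatonin synthesis (-3.41), BZIP52 (-3.30) and CIPK14 (-3.29), which like CIPK15 was dim with glucose, at 1.34. Without replicate 1 of Glc the count was 456, and without replicate 1 or 2 of Mtl it was 414 or 424. With the 4 compared arrays fitted alone it was 464.

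Of the 28 gene lists tested, 8 were called for sugar in air, and none of the 8 was called with an estimated correlation. DNA replication, described above, had a median log2 difference of 0.48. The histone genes H2B.2 and H2B.9 were higher by 1.31 each. The cyclin list was called higher with no single member called (median 0.29, adjusted p = 0.0127; adjusted p = 0.117 with an estimated correlation), and CYCA3-1 stood at 0.92 ± 0.27. Amino acid catabolism had 2 of 4 members lower, GDH2 and the isovaleryl-CoA dehydrogenase gene IVD (-2.29 ± 0.16) (adjusted p = 4.37e-05; adjusted p = 0.09 with an estimated correlation). Alpha-amylase was called lower through RAmy3D, the 1 of 6 members called (adjusted p = 0.0497; adjusted p = 0.152 with an estimated correlation), and AMY1.1, AMY1.2 and AMY1.6 stood at -0.11, -0.10 and -0.08. Likewise sugar signalling rested on CIPK15, 1 of 6 (adjusted p = 0.0127; adjusted p = 0.123 with an estimated correlation). Ethanol fermentation had 1 of 3 members higher, the pyruvate decarboxylase gene PDC2 at 1.07 ± 0.18 (adjusted p = 0.0497; adjusted p = 0.152 with an estimated correlation). Nitrogen transport had NAR2.2 as its 1 called member of 15 (adjusted p = 0.00586; adjusted p = 0.155 with an estimated correlation). The photosynthesis list, which marks green shoot, was lower with none of 11 members called (median -0.31, adjusted p = 0.00586; adjusted p = 0.117 with an estimated correlation), and RBCS stood at -1.05 ± 0.24. Adjusted over the list alone, the counts of these 8 lists were the same except for amino acid catabolism, with 3 lower, and photosynthesis, with 2 lower. Lists not called held single responders. Of 8 trehalose-6-phosphate phosphatase genes 2 were lower, OsTPP1 and OsTPP2 (-1.85), while the list's median was 0.09 and its mean -0.50. The hexokinase gene HXK6, dim with glucose at 1.56, fell by 2.45, the 1 called member of 18 in glycolysis. Of 46 expansin genes 3 were higher and 2 lower, among them EXLA1 (-2.48) and EXPB3 (-1.48) against EXLA3 (1.35) and EXPB8 (1.12); adjusted over the list alone 4 were higher and 2 lower. For trehalose and glycolysis the counts adjusted over the list alone were the same. The endosperm storage list was not called (median -0.22), with GLUA-1 (-1.55 ± 0.28, adjusted p = 0.0176) called of 11, a call lost without replicate 1 of Glc or either Mtl array.

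**Figure D2:**
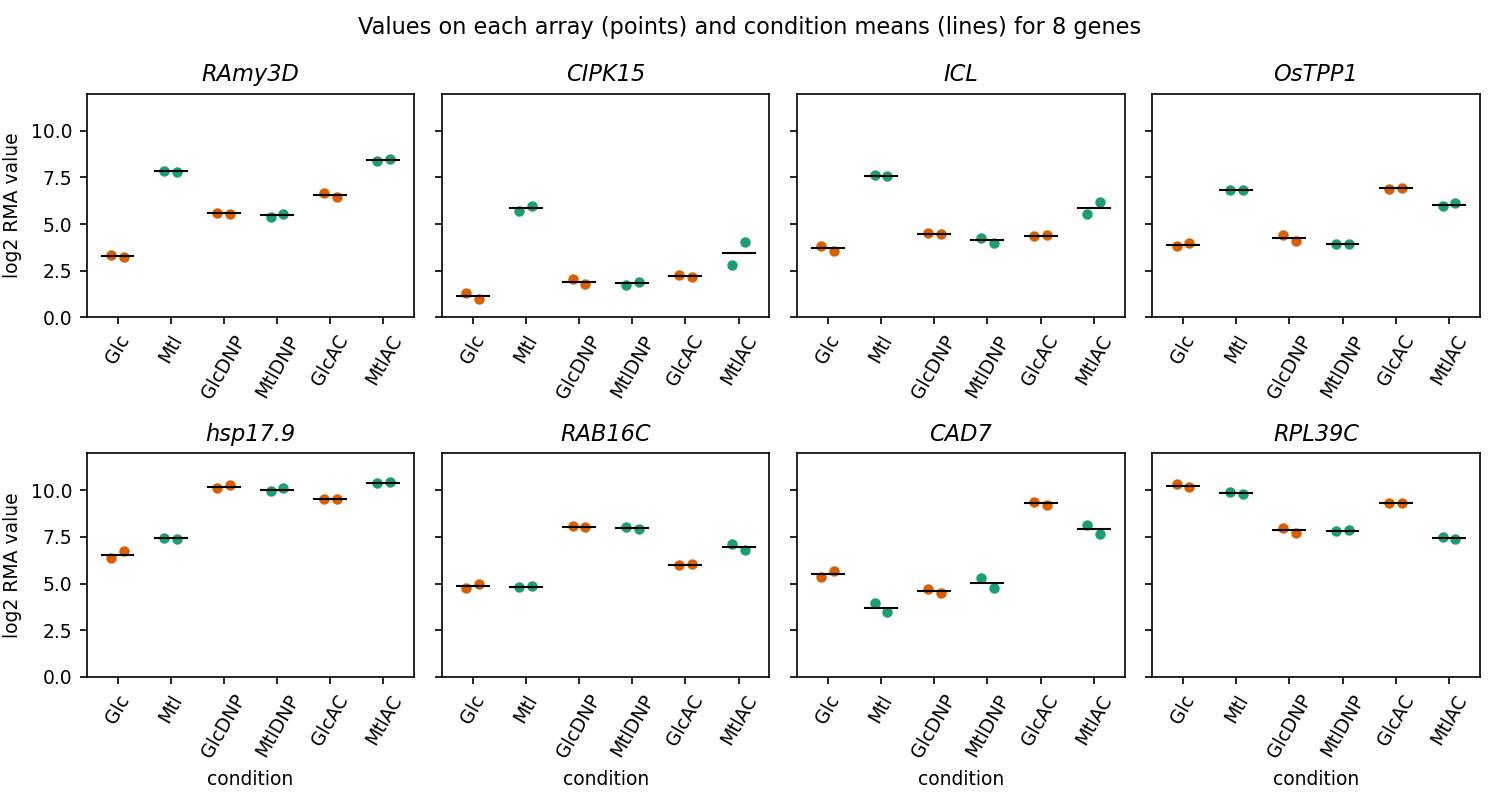
Log2 RMA value (vertical axis) of 8 named genes in the 6 conditions (horizontal axis), with each array as a point, glucose in orange and mannitol in green, and the mean of the 2 arrays as a line. RAmy3D and ICL differed by 4.52 and 3.90 between glucose and mannitol in air. CIPK15, dim with glucose, differed by 4.70, a size that is not settled. Both sugars lay close together with DNP for these genes, at 5.57 and 5.47 for RAmy3D.

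The same sugar comparison with DNP asked whether the response held when energy was lowered. RAmy3D stood at 5.57 ± 0.054 with glucose and 5.47 ± 0.1 with mannitol, CIPK15 at 1.91 ± 0.18 and 1.81 ± 0.1, and ICL at 4.48 ± 0.06 and 4.14 ± 0.19 (log2 difference 0.34 ± 0.22, adjusted p = 0.789). Limma called 5 probes, 4 higher and 1 lower with glucose, and 2622 had an unadjusted p under 0.05. The lectin gene salT (also ML) was 3.14-fold higher with glucose (1.65 ± 0.18, adjusted p = 0.0345), and in air it was lower with glucose (-2.40). Of the other 4 probes, 2 lie in genes without a usable name, LOC4331302 (2.46) and LOC4352127 (2.06), given although outside the rule for named genes and chosen after their values were seen, and 2 are unnamed here. Both of these genes were lower with glucose in air, by log2 differences of -1.09 and -2.64. The count was 0 without replicate 1 or without replicate 2 of GlcDNP, 2 without replicate 1 of MtlDNP and 21 without replicate 2 of MtlDNP. It was also 0 with treat or with the 4 arrays fitted alone. The heat shock list was the 1 list called of 28, higher with glucose at a median of 0.22 with none of its 24 members called, over all probes or adjusted over the list alone (adjusted p = 0.00176; adjusted p = 0.123 with an estimated correlation).

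The interaction tested the difference between these sugar responses directly. It called 435 probes, 369 with a higher and 66 with a lower glucose-over-mannitol difference with DNP than in air. Among named genes the largest were RAmy3D (4.62 ± 0.23, adjusted p = 4.3e-05), OsTIP2;2 (4.44), ASMT (4.29), ICL (4.24) and CIPK15 (4.80 ± 0.47, adjusted p = 0.00101). The size and rank of CIPK15 are not settled because of its dim level in Glc. The smallest among named genes were CAD7 (-2.21), bHLH (-1.92), NAR2.2 (-1.68), the RNA-dependent RNA polymerase gene OsRDR2 (-1.48) and the oxophytodienoate reductase gene opda (-1.44). The count was 287 without replicate 1 of Glc, 241 and 250 without replicates 1 and 2 of Mtl and 281 without replicate 1 of GlcDNP. Of 28 lists 7 were called, and none with an estimated correlation. Amino acid catabolism had IVD (2.48) and GDH2 (2.06) called of 4 (adjusted p = 5.79e-05; adjusted p = 0.0957 with an estimated correlation). DNA replication had a median of -0.57 with none of 40 members called and 6 lower adjusted over the list alone (adjusted p = 1.63e-07; adjusted p = 0.124 with an estimated correlation). Sucrose cleavage had the cell wall invertase gene CIN2 called (2.14 ± 0.36), with 2 members adjusted over the list alone (adjusted p = 0.0152; adjusted p = 0.124 with an estimated correlation). The heat shock, photosynthesis, nitrogen transport and sugar signalling lists had medians of 0.20, 0.39, -0.45 and 0.38. Their adjusted p were 0.0152, 0.0192, 0.0152 and 0.0216, and with an estimated correlation the adjusted p were 0.124, 0.136, 0.21 and 0.136. Called members in these 4 lists were NAR2.2 and CIPK15; adjusted over the list alone 1 heat shock gene was added.

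Under AC the sugar comparison was mostly of genes higher with glucose. The phosphoenolpyruvate/phosphate translocator gene OsPPT3 stood at 6.55 ± 0.038 with glucose and 4.07 ± 0.095 with mannitol (SD, n = 2 arrays each), 5.58-fold higher with glucose (2.48 ± 0.18, adjusted p = 0.00125). RAmy3D was 3.66-fold lower with glucose (-1.87 ± 0.16, adjusted p = 0.00125), at 6.57 ± 0.16 against 8.44 ± 0.06, and ICL was 2.82-fold lower (-1.50 ± 0.22). Of 24 ribosomal protein genes 5 were called higher with glucose and none lower, among them RPL39C (1.88 ± 0.17) and RPS27AB (1.61 ± 0.17). Other large increases were PAC1A (2.10), PDX11 of vitamin B6 synthesis (1.80), the oligosaccharyltransferase gene OST4B (1.77), the brassinosteroid synthesis gene C6-oxidase (also DWARF, 1.75), G1L5 (1.68) and the glutathione transferase gene GSTU1 (1.67). Other large decreases were the storage protein genes prolamin (-1.50) and GLUB-4 (-1.49, dim with glucose at 1.14), the transcription factor gene DREB1I (-1.49), OsC3H37 (-1.28), CIPK21 (-1.20) and HXK6 (-1.19).

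In total 975 probes were called under AC, 831 higher and 144 lower with glucose, or 85.2% higher. After quantile re-normalization 877 were called and 68.2% were higher. The count was 394 and 295 without replicates 1 and 2 of GlcAC, 581 without replicate 1 of MtlAC and 255 with the 4 arrays fitted alone. Of 28 lists 5 were called, and 3 of them also with an estimated correlation. Ribosomal proteins had 5 of 24 members higher and none lower (median 0.77, adjusted p = 3.27e-16; adjusted p = 0.0101 with an estimated correlation). Heat shock proteins were lower (median -0.54, adjusted p = 8.06e-08; adjusted p = 0.0101 with an estimated correlation), with HSP16.9C lower (-1.08) and HSP17.9B higher (1.09) among 24. Endosperm storage, a list that marks another tissue, was lower too, with prolamin and GLUB-4 called of 11 and 3 lower adjusted over the list alone. Its median was -0.50 (camera adjusted p = 7.84e-05, and adjusted p = 0.0361 with an estimated correlation). Levels were low, at 2.32 with glucose and 3.82 with mannitol for prolamin and 1.14 and 2.63 for GLUB-4. The MtlAC arrays had the narrower range, and the list was not compared with probes of like level. The tricarboxylic acid cycle list had 2 of 10 members higher, the succinate dehydrogenase genes SDH5 (1.35) and SDH3-2 (1.10) (adjusted p = 2.77e-06; adjusted p = 0.0722 with an estimated correlation). The late embryogenesis abundant (LEA) list had RAB21 called lower (-1.09) of 9 (median -0.63, adjusted p = 2.77e-06; adjusted p = 0.0915 with an estimated correlation). Adjusted over the list alone, the counts of the ribosomal, heat shock, tricarboxylic acid cycle and LEA lists were the same.

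The interaction of sugar and AC called 423 probes, 369 with a higher and 54 with a lower glucose-over-mannitol difference under AC than in air. Both interactions subtract the same difference between the Glc and Mtl arrays, so they are not independent of each other. The sugar difference of OsTPP1 was -2.90 in air, while under AC its level was 6.93 ± 0.032 with glucose and 6.04 ± 0.082 with mannitol (interaction 3.78 ± 0.24, adjusted p = 0.00105). The next largest among named genes were ASMT (3.25), the strigolactone receptor gene D14 (3.00) and CIPK15 (3.50) and CIPK14 (3.22), both dim in Glc. The smallest among named genes were CAD8A (-2.06), NAR2.2 (-1.85), the aluminium transporter gene Nrat1 (-1.73), the replication protein A gene OsRPA70b (-1.52) and ERG1 (-1.41). This count moved with every array left out. It was 102 and 214 without replicates 1 and 2 of Glc, 73 and 87 without those of Mtl, 77 and 72 without those of GlcAC, and 107 and 190 without those of MtlAC. It was 236 after quantile re-normalization, 756 without dim probes and 707 with trend and robust. Of 28 lists 13 were called and none with an estimated correlation. The ribosomal list had RPL18 (1.68) and RPL39C (1.49) higher of 24, and 4 higher adjusted over the list alone (median 0.58, adjusted p = 1.51e-08; adjusted p = 0.0516 with an estimated correlation). Trehalose metabolism had OsTPP1 and OsTPP2 (1.53) higher of 8, and the same number adjusted over the list alone (adjusted p = 0.019; adjusted p = 0.132 with an estimated correlation). The antioxidant list had the glutaredoxin gene GRXS2 (2.22) and the catalase gene CAT-A (2.12) higher of 41, and 5 higher adjusted over the list alone (adjusted p = 0.0343; adjusted p = 0.132 with an estimated correlation). Sucrose cleavage had CIN2 (2.47) higher of 17, and 3 higher adjusted over the list alone (adjusted p = 0.00652; adjusted p = 0.0904 with an estimated correlation). The heat shock list had HSP16.9C (-1.24) lower of 24, and 1 lower adjusted over the list alone (adjusted p = 0.000364; adjusted p = 0.0516 with an estimated correlation). Amino acid catabolism had IVD (1.21) higher of 4, and 2 higher adjusted over the list alone (adjusted p = 0.00233; adjusted p = 0.0904 with an estimated correlation). The tricarboxylic acid cycle list had no called member of 10, and 3 higher adjusted over the list alone (median 0.66, adjusted p = 0.00184; adjusted p = 0.132 with an estimated correlation). DNA replication had OsRPA70b lower of 40 (median -0.48, adjusted p = 0.000374; adjusted p = 0.132 with an estimated correlation), and cyclins had none of 19 called (median -0.43, adjusted p = 0.00229; adjusted p = 0.085 with an estimated correlation). LEA had none of 9 called (median -0.48, adjusted p = 0.00598; adjusted p = 0.179 with an estimated correlation), beside an endosperm storage median of -0.28. The hemoglobin list had none of 4 called and 1 lower adjusted over the list alone (median -0.66, adjusted p = 0.0124; adjusted p = 0.132 with an estimated correlation). Nitrogen transport and sugar signalling had NAR2.2 and CIPK15 as their called members (adjusted p = 0.00208 and adjusted p = 0.0332, and adjusted p = 0.132 for each with an estimated correlation). For these last 2 lists, DNA replication, cyclins and LEA the counts adjusted over the list alone were the same.

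The additive fit over the 6 condition means asked for sugar differences common to the 3 environments. Limma called 0 probes, with 2258 at an unadjusted p under 0.05, and the same model on all 12 arrays called 12 probes.

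DNP with glucose changed more probes than sugar did. With no sample before 24 h, rises and falls here and under AC are differences between conditions. Whether germination had gone equally far in each condition was not tested. Of 24 heat shock protein genes 17 rose and 1 fell. Those that rose included hsp17.9 (also HSP17.9A), from 6.55 ± 0.28 to 10.2 ± 0.12 (SD, n = 2 arrays each), 12.5-fold (3.64 ± 0.18, adjusted p = 5.77e-06), and HSP18.1 (3.42), HSP17.7 (3.27) and HSP17.4 (3.07). The heat shock factor gene HSF07 rose 11.8-fold (3.57 ± 0.19). The dehydrin gene RAB16C rose 8.94-fold (3.16 ± 0.17, adjusted p = 5.77e-06). The transcription factor gene CBF3 (also DREB1A) rose by 3.21 and RH3 by 3.11. The largest decreases among named genes were OST4B, 20.3-fold (-4.34 ± 0.37, adjusted p = 4.04e-05), Os-UGD4 (-4.28), the beta-expansin gene EXPB8 (-3.80), BHLH170 (-3.72), HSP17.9B (-3.20), CAD8A (-3.16), FNR (-3.08) and the methyltransferase gene COA20 (-3.05). RAmy3D rose by 2.28 ± 0.16.

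In total 5113 probes were called with DNP and glucose, 1712 higher and 3401 lower. Of 28 lists 10 were called, of which heat shock and ribosomal proteins were also called with an estimated correlation. Heat shock proteins had 17 of 24 members higher and 1 lower, HSP17.9B (median 2.23, adjusted p = 7.27e-15; adjusted p = 0.00279 with an estimated correlation). Ribosomal proteins had 15 of 24 lower and none higher (median -1.10), led by RPL27 (-2.55) and RPL39C (-2.40). Camera gave adjusted p = 1.41e-12, and adjusted p = 0.0209 with an estimated correlation. Ribosomal genes were bright, with RPL39C at 10.26 and RPS10 at 9 in Glc. In this contrast the 3665 probes with the highest level in mannitol arrays had a median of -0.874. Some members of the tricarboxylic acid cycle and glycolysis lists were bright too, with SDH3-2 at 8.68 and FBA1 at 10.94 in Glc. Whether the ribosomal list or any other list moved beyond probes of like brightness was not tested in any comparison. All 9 LEA genes matched by symbol were higher (median 1.84, adjusted p = 5.47e-10, and adjusted p = 0.0517 with an estimated correlation), with RAB16B at 2.75 and EM at 2.47. DNA replication had 16 of 40 lower and none higher (median -0.81, adjusted p = 1.01e-08; adjusted p = 0.0731 with an estimated correlation), with ORC6 at -2.92 and H2B.9 at -2.07. The tricarboxylic acid cycle list had 8 of 10 lower (adjusted p = 4.96e-07; adjusted p = 0.057 with an estimated correlation), with SDH3-2 at -2.32, SDH5 at -2.28, SDH3-1 at -1.68 and the succinyl-CoA ligase gene SCS-alpha at -1.13. Glycolysis had 6 of 18 lower and 1 higher (adjusted p = 0.037; adjusted p = 0.137 with an estimated correlation), with the aldolase gene FBA1 at -2.66 and HXK2 at -2.12. The abscisic acid list had NCED3 (1.43), ABA8OX3 (1.24) and OsSAPK5 (1.11) higher of 25 (adjusted p = 0.037; adjusted p = 0.137 with an estimated correlation), genes that respectively make, break down and signal for the hormone. The WRKY list had 3 of 6 transcription factor genes higher, OsWRKY62 at 2.20 (adjusted p = 0.037; adjusted p = 0.141 with an estimated correlation). Alpha-amylase had RAmy3D called of 6 (adjusted p = 0.037; adjusted p = 0.139 with an estimated correlation). The endosperm storage list was higher beside these, with GLUA-1 (1.84) called of 11 (median 0.34, adjusted p = 0.0479, and adjusted p = 0.141 with an estimated correlation). OLE18, the 1 oil body gene matched by symbol, rose by 1.95 ± 0.17. Adjusted over the list alone, the counts of the 10 called lists were the same. Expansins were not called (median 0.07, mean -0.26), with 2 of 46 higher and 10 lower, and the same number adjusted over the list alone.

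DNP with mannitol gave 5983 called probes, 2167 higher and 3816 lower. HSP18.1 rose 9.46-fold (3.24 ± 0.26, adjusted p = 2.46e-05), HSF07 by 3.22, RAB16C by 3.13, GAP1 by 3.00, HSP16.9C by 2.97, HSP17.4 by 2.95, HSF10 by 2.94 and HSP17.7 by 2.92. Among named genes the chitinase gene CH16 (also Cht1) had the largest decrease (log2 difference -4.91 ± 0.22, adjusted p = 2.38e-06). It was followed by ASMT (-4.89), the chitinase gene CH6 (-4.73), the isochorismate synthase gene OsICS (-4.29), salT (-4.26), EXPB6 (-4.03), CIPK15 (-4.03) and LSD1 (-3.87). RAmy3D, higher with DNP on glucose, was lower with DNP on mannitol (-2.35 ± 0.16, adjusted p = 1.07e-05), and ICL fell by 3.46.

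Of 28 lists 9 were called with DNP and mannitol, of which heat shock and ribosomal proteins were also called with an estimated correlation. Heat shock proteins had 17 of 24 higher and 1 lower (median 1.75, adjusted p = 1.67e-10; adjusted p = 0.008 with an estimated correlation). Ribosomal proteins had 12 of 24 lower (median -1.0, adjusted p = 9.78e-11; adjusted p = 0.0294 with an estimated correlation), with RPL18 at -3.63. LEA genes had 8 of 9 higher (adjusted p = 4.23e-08; adjusted p = 0.0814 with an estimated correlation). The tricarboxylic acid cycle had 5 of 10 lower (adjusted p = 2e-05; adjusted p = 0.0814 with an estimated correlation), and glycolysis had 6 of 18 lower and 1 higher (adjusted p = 0.00572; adjusted p = 0.0814 with an estimated correlation). Autophagy had 4 of 8 lower, the genes ATG8A (-1.41), ATG8B (-1.15), ATG8D (-1.12) and ATG8C (-1.02) (adjusted p = 0.0467; adjusted p = 0.307 with an estimated correlation). Amino acid catabolism had IVD (-2.66), GDH1 (-1.58) and GDH2 (-1.47) lower of 4 (adjusted p = 0.013; adjusted p = 0.107 with an estimated correlation). The antioxidant list had 12 of 41 lower and 3 higher, with GRXC8 at -2.37 and CAT-A at -2.04 (adjusted p = 0.0467; adjusted p = 0.202 with an estimated correlation). DNA replication had 2 of 40 lower, ORC6 (-1.69) and FEN1A (-1.15) (adjusted p = 0.0342; adjusted p = 0.321 with an estimated correlation). Adjusted over the list alone, the counts of these 9 lists were the same. OLE18 rose by 2.07 ± 0.17, and the endosperm storage median was 0.49.

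The additive fit called 4693 probes for DNP across both sugars, 1458 higher and 3235 lower (31.1% higher, and 42.3% higher of 4724 after quantile re-normalization). Among named genes the largest increases were HSF07 (3.39 ± 0.19, adjusted p = 0.00447), HSP18.1 (3.33), RAB16C (3.14), hsp17.9 (3.13) and HSP17.7 (3.09). The largest decreases among them were OST4B (-3.89), CH16 (-3.76), EXPB8 (-3.74), CH6 (-3.52) and Os-UGD4 (-3.38). Without replicate 2 of each condition the count was 2463.

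Under AC with glucose, RAmy3D rose 9.65-fold (3.27 ± 0.16, adjusted p = 6.12e-06) and OsTPP1 rose 8.14-fold (3.03 ± 0.17, adjusted p = 1.26e-05), both genes that were higher with mannitol than with glucose in air. CAD7 rose 13.9-fold, from 5.51 ± 0.22 to 9.3 ± 0.12 (3.79 ± 0.26, adjusted p = 3.64e-05). DREB1I rose by 3.69, OsPPT3 by 3.38, the auxin-responsive gene SAUR39 by 3.14, RH3 by 3.06 and hsp17.9 by 2.97. The alcohol dehydrogenase gene Adh2 rose by 1.54 ± 0.20, and AOX1, the 1 alternative oxidase gene matched by symbol, fell by 1.44 (SE 0.19). The largest decreases among named genes were CAD8A, 10.1-fold (-3.33 ± 0.27, adjusted p = 0.000104), Os-UGD4 (-3.03), HSP17.9B (-2.94), CH16 (-2.57), the germin-like gene GER4 (-2.42), EXPB8 (-2.38), EXPB6 (-2.38) and the kinesin gene KIN5C (-2.29).

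In total 1925 probes were called under AC with glucose, 735 higher and 1190 lower. The count was 1280 without replicate 2 of Glc (645 higher and 635 lower) and 1218 without replicate 2 of GlcAC (499 and 719). The excess of lower calls was thus absent without that Glc array, and it was small after quantile re-normalization (758 higher and 833 lower) and with treat (285 and 298). Of 28 lists 13 were called, and 7 of them also with an estimated correlation. Of these 7, heat shock had 15 of 24 higher and 1 lower (median 1.49, camera adjusted p = 3.35e-15). Ribosomal proteins had 3 of 24 lower (median -0.73, adjusted p = 1.23e-11). DNA replication had 8 of 40 lower (adjusted p = 4.3e-10), among them H2B.9 (-2.01) and MCM3 (-1.81, dim in GlcAC at 1.51). The others were LEA, with LIP9 (1.27), EM (1.16) and RAB16C (1.12) higher of 9 (adjusted p = 5.6e-08); WRKY, with OsWRKY62 (2.28) and OsWRKY24 (1.16) higher of 6 (adjusted p = 0.000611); cyclins, with CYCA3-1 (-1.52), CYCA2-1 (-1.21) and CYCB2-1 (-1.06) lower of 19 (adjusted p = 0.000898); and cell wall, with the cellulose synthase gene CESA1 (-1.37) and CSLC2 (-1.26) lower of 36 (adjusted p = 0.00661). Ethanol fermentation had Adh2 called of 3, with PDC2 at 0.68 ± 0.18 (adjusted p = 0.00934; adjusted p = 0.0728 with an estimated correlation). Glycolysis had HXK6 (2.77, dim in Glc at 1.56) called of 18 (adjusted p = 0.0168, and adjusted p = 0.0728 with an estimated correlation). The tricarboxylic acid cycle list was lower with none of 10 called (median -0.61, adjusted p = 0.000979; adjusted p = 0.0873 with an estimated correlation). Alpha-amylase had RAmy3D called of 6 (adjusted p = 0.00585; adjusted p = 0.0634 with an estimated correlation). Expansins had 10 of 46 lower and 2 higher (adjusted p = 0.0443; adjusted p = 0.0806 with an estimated correlation). The hemoglobin gene NSHB1 fell by 2.09, the 1 called of 4 (adjusted p = 0.0329; adjusted p = 0.19 with an estimated correlation). Adjusted over the list alone, ribosomal proteins had 4 lower, cell wall 3 lower, expansins 11 lower and glycolysis 2 higher, and the counts of the other called lists were the same. The endosperm storage list was not called (median 0.15), with GLUA-1 (1.12 ± 0.28, adjusted p = 0.0367) called of 11, a call lost without any 1 of the 4 compared arrays and after quantile re-normalization. OLE18 stood at 0.63 ± 0.17 (adjusted p = 0.0544).

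Under AC with mannitol, 4475 probes were called, 1304 higher and 3171 lower (29.1% higher, and 41.2% higher of 4339 after quantile re-normalization). CAD7 rose 18.3-fold (4.19 ± 0.26, adjusted p = 1.24e-05), HSP16.9C by 3.28, DREB1I by 3.23, HSP18.1 by 3.06, HSP17.7 by 3.04, HSP17.4 by 3.02, hsp17.9 by 2.99 and OsC3H37 by 2.78. ASMT was 26.3-fold lower (-4.72 ± 0.22, adjusted p = 6.13e-06), followed by CH16 (-4.28), CH6 (-4.08), GER4 (-3.66), the lipid transfer protein gene LTP (-3.47), EXPB6 (-3.45), the arginine decarboxylase gene ADC2 (-3.35) and the lipoxygenase gene LOX1.1 (-3.27). PDC2 and Adh2 rose by 1.40 and 1.22, AOX1 fell by 1.18, and ICL fell by 1.72.

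Of 28 lists 7 were called under AC with mannitol, of which ribosomal and heat shock proteins were also called with an estimated correlation. Ribosomal proteins had 18 of 24 lower (median -1.45, adjusted p = 7.25e-15; adjusted p = 0.0127 with an estimated correlation). Heat shock proteins had 16 of 24 higher and 1 lower (median 1.95, adjusted p = 8.89e-13; adjusted p = 0.00458 with an estimated correlation). LEA genes had 6 of 9 higher, RAB16C at 2.11 (adjusted p = 6.24e-07; adjusted p = 0.0917 with an estimated correlation). The tricarboxylic acid cycle had 5 of 10 lower, SDH5 at -1.99 (adjusted p = 4.19e-06; adjusted p = 0.0917 with an estimated correlation). WRKY genes had OsWRKY62 (2.33) and OsWRKY71 (1.17) higher of 6, endosperm storage none of 11 (median 0.52), and ethanol fermentation PDC2 and Adh2 of 3. Their adjusted p were 0.0112, 0.0117 and 0.0141, and for each the adjusted p was 0.106 with an estimated correlation. Adjusted over the list alone, the counts of these 7 lists were the same. OLE18 rose by 1.41 ± 0.17. Expansins were not called (median 0.11, mean -0.23), with 1 of 46 higher and 9 lower, and the same number adjusted over the list alone.

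The additive fit called 1589 probes for AC across both sugars, 475 higher and 1114 lower (29.9% higher, and 40.7% higher of 1308 after quantile re-normalization). Among named genes the largest increases were CAD7 (3.99 ± 0.50, adjusted p = 0.0195), DREB1I (3.46), hsp17.9 (2.98), HSP17.4 (2.71) and OsC3H37 (2.70). The largest decreases among them were CH16 (-3.42), CH6 (-3.17), GER4 (-3.04), HSP17.9B (-2.99) and EXPB6 (-2.92). Without replicate 2 of each condition the count was 178, with 90 higher and 88 lower, so that the excess of lower calls was absent. Without replicate 1 it was 642, with 226 higher and 416 lower.

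**Figure D3:**
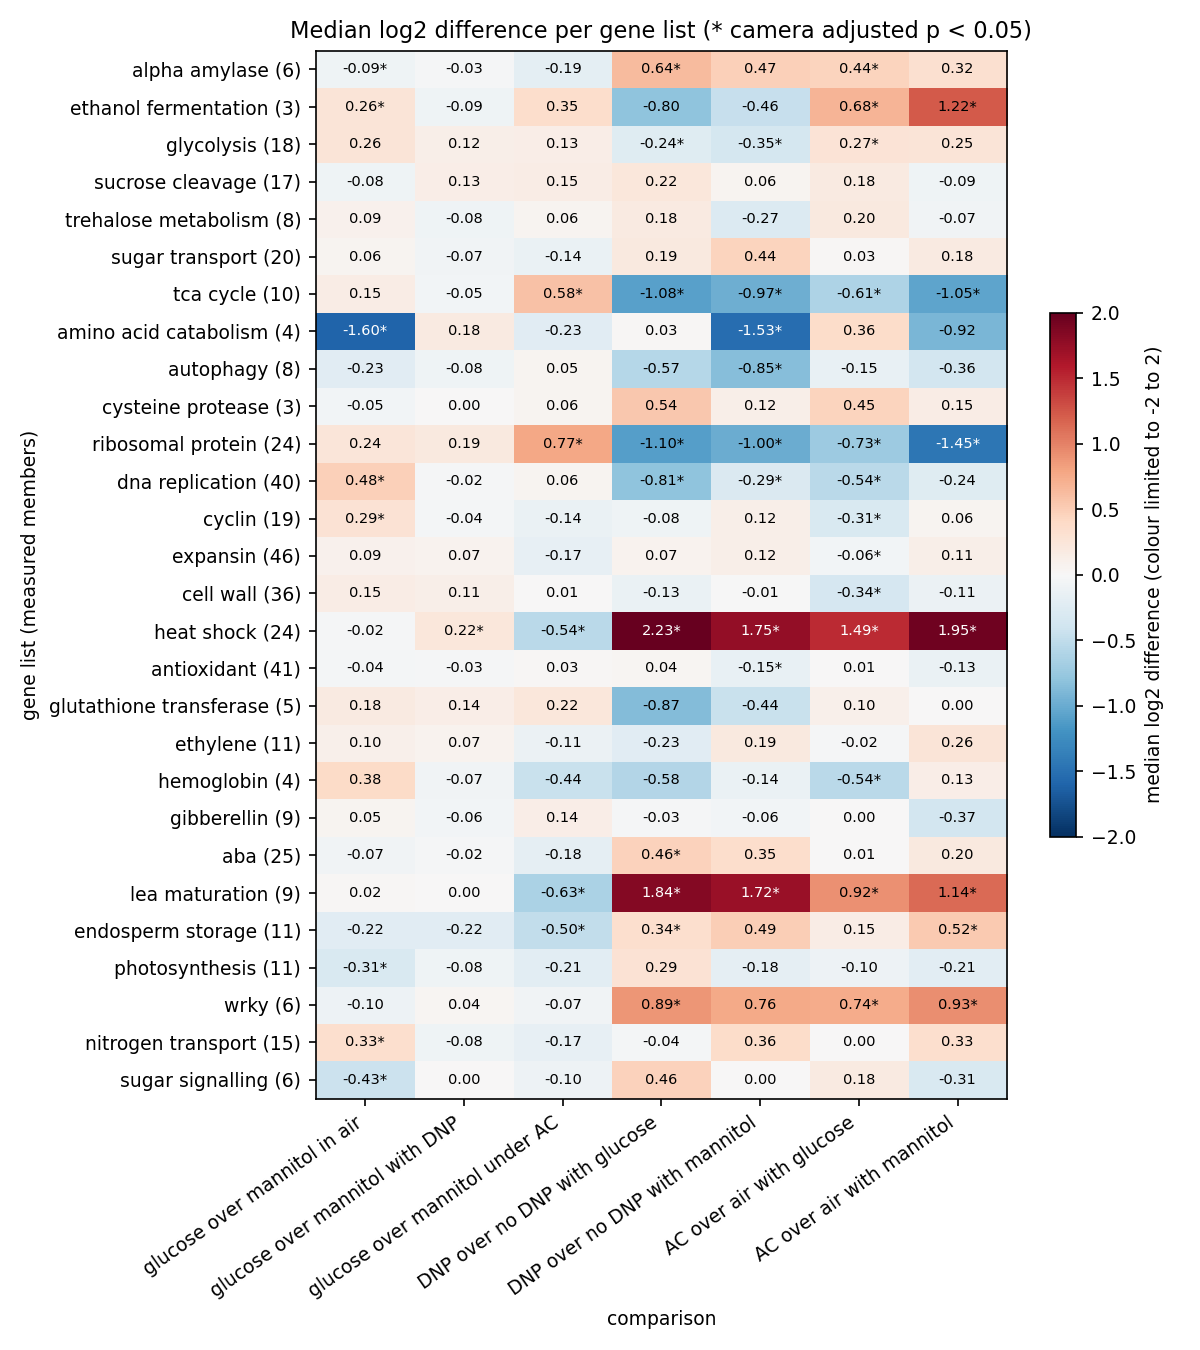
Median log2 difference (colour and printed value) of each of the 28 tested gene lists (vertical axis, with the number of measured members) in 7 comparisons (horizontal axis), with a star where camera's adjusted p was under 0.05 at the preset correlation. Heat shock genes had medians of 2.23, 1.75, 1.49 and 1.95 with DNP and under AC, and ribosomal proteins -1.10, -1.0, -0.73 and -1.45. The ribosomal genes were bright, and no list was compared with probes of like brightness.

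To compare the responses to loss of sugar, energy and oxygen, glucose withdrawal in air (mannitol over glucose), DNP with glucose and AC with glucose were set side by side. All use the 2 Glc arrays. Withdrawal and DNP shared 116 higher and 134 lower calls, with 53 called in opposite directions, against 26.2 and 16 for independent lists. Withdrawal and AC shared 132 higher and 90 lower, with 48 opposite, against 11.3 and 5.59. DNP and AC shared 421 higher and 985 lower, with 21 opposite, against 34.3 and 110. In simulations in which no group differed and all arrays were simulated, the mean number of shared calls was at most 0.01. Hardly any probe is called when no group differs, so that number is no baseline for these overlaps. The counts for independent lists treat all probes as equally likely to be called. With DNP and glucose, however, 44.9% of the brightest and 0.589% of the dimmest probes in mannitol arrays were called lower. In all 3 responses 77 probes were higher and 87 lower. The correlations across probes, which are not independent replicates, were 0.27, 0.354 and 0.703, and the simulated correlations 0.499, 0.5 and 0.499. The covariances were 0.0998, 0.0916 and 0.329 beside simulated covariances of 0.0436, 0.0437 and 0.0435. The 2 Glc arrays were too few to be split into sets of at least 2, so part of the excess in shared calls may come from the shared arrays. Pairs of responses that share no array gave 55 higher and 722 lower for withdrawal under AC with DNP on glucose (correlation 0.541), and 492 higher and 2097 lower for DNP on glucose with AC on mannitol (0.702), with 14 and 41 opposite. The reciprocal pair, DNP on mannitol with AC on glucose, gave 307 higher and 804 lower, with 84 opposite (0.511). Withdrawal with DNP, with 5 calls, shared 1 call in the same direction and 1 in the opposite direction with AC on glucose. Withdrawal in air correlated at -0.0331 with withdrawal in DNP and at 0.162 with withdrawal under AC. DNP on glucose and on mannitol shared 847 higher and 2384 lower calls (0.754), and AC on both sugars 376 and 874 (0.627). The DNP and MtlAC arrays had a narrower range of values than the air arrays. Falls of bright probes that go with this range could add to the shared lower calls and to the correlations, also without a shared array. The overlaps were not recomputed after quantile re-normalization or by level, so this stays open.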

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

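The tests of spread, range, a deviating array, an offset and the size of a response, and the values by level, were chosen after the results had been seen; the interactions, the alternatives and the tests of a swap of DNP arrays and of an even shrinkage were set beforehand.

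The glucose-over-mannitol difference depended on the environment by a test of the difference itself for 435 probes with DNP and 423 under AC. Both tests subtract the same difference between the Glc and Mtl arrays, so genes found in both are not independent results. With DNP, the genes named by the rule were CIPK15 (4.80), RAmy3D (4.62), OsTIP2;2 (4.44), ASMT (4.29) and ICL (4.24), and in the other direction CAD7 (-2.21), bHLH (-1.92), NAR2.2 (-1.68), OsRDR2 (-1.48) and opda (-1.44), all as log2 interactions. Under AC they were OsTPP1 (3.78), CIPK15 (3.50), ASMT (3.25), CIPK14 (3.22) and D14 (3.00), and CAD8A (-2.06), NAR2.2 (-1.85), Nrat1 (-1.73), OsRPA70b (-1.52) and ERG1 (-1.41). The sizes and ranks of CIPK15 in both lists and of CIPK14 are not settled, since both genes were dim in Glc, at 1.15 and 1.34.

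Few sugar differences were called with DNP. A wider spread between DNP arrays as the whole account is argued against by the sugar difference itself: over the probes called in air, its slope on that in air was -0.0319, and it lay between -0.0389 and -0.025 in the pairs of 1 glucose and 1 mannitol DNP array. After all arrays were given 1 distribution 5 probes were called. This count cannot decide on a narrower range, since re-normalization scales the differences between DNP arrays and their spread together. The SD of values was 1.639 to 1.675 with DNP and 1.808 to 1.857 in air. An even narrowing of that size would leave most of the sugar difference, and the slope of -0.0319 argues against it as the whole account. A swap of 1 glucose and 1 mannitol DNP array would set DNP arrays apart on the score of these probes, and their largest difference was 0.0637 of that in air. The mean signed difference with DNP was -0.0474 of that in air, so a candidate explanation is that the response to sugar is lost when energy is lowered; a mix-up before the arrays, or effects of DNP other than on energy, stay open and were not tested.

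Sugar differences under AC were mostly higher with glucose. The narrower range of the mannitol AC arrays may account for part of this, since the share moved from 85.2% to 68.2% once all arrays were given 1 distribution. Most calls were still higher with glucose, which argues against range as the whole account with all arrays in. That setting was not repeated without single arrays. Without re-normalization, leaving out 1 AC array left the share at 79.5% or more. Over probes called in either AC response, the response with glucose had a slope of 0.632 on that with mannitol, but as 4475 probes were called with mannitol and 1925 with glucose this restates the counts, so a weaker AC response with glucose stays open.

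With DNP the range of values was narrower and more probes were called lower than higher, though by how much depended on the setting: 33.5% of calls were higher with glucose and 36.2% with mannitol, 42.7% and 44.4% after quantile re-normalization, and 42.8% and 49.8% with no size threshold. An even shrinkage of all values stays open: from the dimmest to the brightest probes in mannitol arrays the median log2 difference with DNP and glucose was 0.229, 0.183, 0.0679, -0.244 and -0.874, the order that shrinkage predicts, and although the level explained a share of 0.123 of the variance, below the bound set beforehand, that bound was wrong because responses of single genes add variance that shrinkage does not forbid. A difference in range as the whole account of the excess stays open too, since after quantile re-normalization the share of higher calls reached 47.9% with mannitol without replicate 2 of MtlDNP. An offset between arrays is argued against by median-centring, after which 30.7% of calls were higher with DNP and glucose. Of the 3665 probes with the highest level in mannitol arrays 44.9% were called lower with DNP and glucose, and 10.4% higher, and of the 9161 with the lowest level 0.589% and 2.61%; a change in total RNA per embryo was not tested and stays open, because the arrays measure relative levels.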

How the results depend on the processing

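No gene value and no list value that was called in the main run or in the alternative changed direction. A change of sign in a value called in neither was not counted. Of the recomputed values of 537 gene results, 6589 were on the same side of the threshold, 463 lost their call and 152 gained one. For the 107 list results these numbers were 335, 70 and 2. The number of arrays limits all of them, and with 1 array left in a condition that array is assumed to vary like the others. Where a count moved, the cause was not tested unless the alternative's construction gives it.

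For the interaction of sugar and AC (423 calls) the count was 236 after quantile re-normalization, 756 without dim probes, 707 with trend and robust, 67 with treat and 3129 for averaged arrays with no p, and 72 to 214 without 1 array. With no size threshold the counts were 9085 and 11712 for DNP with glucose and mannitol, 3077 and 8812 for AC with glucose and mannitol and 7401 for DNP across sugars. With treat, which tests against a fold of 1.5, they were 2771, 2909, 583, 2096 and 1425, and for sugar in air 282, with DNP 0 and under AC 132, for the interaction with DNP 172 and for AC across sugars 178. With the compared groups alone, which leaves fewer arrays, sugar in air had 464, with DNP 0 and under AC 255. For averaged arrays with no p these were 1332, 826 and 1884, and the interaction with DNP 2692. Without 1 array the ranges were 414 to 539 for sugar in air, 0 to 21 with DNP, 295 to 730 under AC, 1218 to 1714 for AC with glucose and 241 to 405 for the interaction with DNP. Without 1 replicate they were 2463 to 4644 for DNP and 178 to 642 for AC across sugars. All 12 arrays as observations gave 2833 for AC across sugars and 12 for sugar across environments, against 0. Gene list calls were 73 of 252, and 16 with an estimated correlation.

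With no size threshold, calls shared in the same direction were 421 for withdrawal in air and DNP with glucose (250 with it), 357 for withdrawal in air and AC with glucose (222) and 2425 for DNP and AC with glucose (1406). With the size threshold, pairs that share no array shared 777 (withdrawal under AC and DNP with glucose), 1 (withdrawal with DNP and AC with glucose), 2589 (DNP with glucose and AC with mannitol), 1111 (DNP with mannitol and AC with glucose), 3231 (DNP with each sugar), 1250 (AC with each sugar), and 0 and 95 (withdrawal in air and withdrawal with DNP or under AC).

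The replicate numbers did not pair the arrays: the 15 correlations of deviations between same-numbered arrays of different conditions ran from -0.0214 to 0.0873, none over 0.1. With the replicate block the 9 counts were 723, 2, 968, 5126, 6004, 1906, 4502, 411 and 363, in the order of sugar in air, with DNP and under AC, DNP with glucose and mannitol, AC with glucose and mannitol and the interactions with DNP and AC, and list calls 71.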

Other observations

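The tests of the withdrawal genes and of the splits, and which genes and lists are described, were chosen after the results had been seen; the contrasts, the list tests and the additive fit were planned.

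Several genes outside the groups described above changed. COX5c, of cytochrome c oxidase, was 1 of 2 respiratory chain genes matched by symbol. It fell by 2.13 with DNP and glucose, by 2.50 with DNP and mannitol and by 1.80 under AC with mannitol. Under AC with glucose it stood at -0.70 ± 0.21 (adjusted p = 0.0789), and under AC it was higher with glucose by 1.03 ± 0.21 (adjusted p = 0.0284). Among ethylene genes, with DNP and glucose the receptor gene ERS1 fell by 1.55 and ETR4 rose by 1.02, and ETR2 fell by 1.11 under AC with mannitol. ERS1 also fell under AC with glucose, by 1.02, a call lost without either Glc array or replicate 1 of GlcAC and after quantile re-normalization, and stood at -0.93 with DNP and mannitol and -0.86 under AC with mannitol. The glutathione transferase gene GSTF2 fell by 1.53 and 1.67 with DNP on glucose and mannitol and by 1.57 and 1.83 under AC with glucose and mannitol. The cysteine protease gene CP1 rose by 1.25 and 1.19 with DNP on glucose and mannitol and by 1.15 under AC with mannitol, and stood at 0.91 ± 0.22 under AC with glucose (adjusted p = 0.0298), below the size threshold. These ethylene, glutathione transferase and cysteine protease lists were called in none of the 9 contrasts, as were sugar transport and gibberellin. Of these, sugar transport in air (median 0.06, mean -0.05) and ethylene under AC with mannitol (median 0.26, mean -0.02) had a median and mean of opposite sign.

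Of the sugar transporters, OsSWEET4 was lower with glucose in air by 1.16 (log2 difference -1.16 ± 0.19) and fell by 1.52 with DNP and mannitol, and MST3 fell by 1.08 and 1.31 with DNP on glucose and mannitol. OsSWEET12 and OsSUT5 rose by 1.16 and 1.12 with DNP and mannitol. OsSWEET12 was dim, at 1.02 in Mtl, close to the 5th percentile of those arrays (1.001 and 1.013), and at 2.18 in MtlDNP. The size of its rise is therefore not settled. With glucose it did not rise, at 1.43 in Glc and 1.34 in GlcDNP. The gibberellin synthesis gene GA20OX3 was lower with glucose in air (-1.22), and GID2 fell by 1.11 with DNP and glucose.

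A hypothesis was that DNP and AC move the genes of glucose withdrawal the same way even with glucose present. The genes were called from 1 glucose array and the response was taken against the other, and again with the arrays exchanged. The lower of both mean signed log2 differences was 0.492 for AC with glucose and 0.468 for DNP with glucose. Because the 2 arrays may hold the same RNA, a deviation of that RNA would enter both the choice of genes and the response, so the hypothesis and such a deviation cannot be told apart here. On the score of the probes called in air, GlcDNP lay at 63% and 63.9% of the way from Mtl to Glc, and GlcAC at 65.7% and 64.4%. With mannitol these probes moved the other way, toward Glc, with MtlDNP at 69.3% and 67% and MtlAC at 43.6% and 40.4%. The score rests on probes chosen from the same air arrays, so it has the same limit. Whether the narrower range of values on the DNP and MtlAC arrays moved these probes was not tested either.

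For glucose over mannitol across environments the 10 splits of 6 condition means are too few for a share under 0.05. The real split called 0 probes with limma, with 2258 at an unadjusted p under 0.05, and the highest of the other splits called 0; with 0 calls the comparison of splits carries no information.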
